A study of Homo sapiens with 6 samples.

How the data were processed

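Polyadenylated RNA from 6 samples of HEK293 cells was sequenced, 3 libraries of cells that carried a scrambled control shRNA and 3 of cells that carried an shRNA against PRPF39. HEK293 is an established human embryonic kidney cell line. Per the labels' protocols, the shRNAs were delivered by lentivirus, cells with an integrated construct were kept by puromycin selection, and the polyadenylated RNA was fragmented before library preparation. Groups and replicate numbers were read from the sample titles. The labels do not say whether the replicates were separate transductions or cultures, so the p-values measure the spread between these libraries, which may be technical.

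Each library came as 1 table of transcripts, 203028 in every file, with length, effective length, TPM and number of reads, per the file headers. The authors deposited estimated counts: the read numbers are the quantifier's estimates, mostly not whole, with no scaling for depth or length. The deposited TPM values use each library's own effective lengths and have the same sum in every library. Per the submitters' processing notes the tools were cutadapt 2.1, STAR 2.7.9a, Salmon 0.11.1 and DESeq2 1.32.0, with build hg38. Those notes give no options or annotation release that could be used here. Salmon shares reads that match several transcripts between them by a probabilistic model, so a transcript's estimate depends on those of its near-identical relatives. The files carry no bootstrap estimates, and that uncertainty therefore entered the tests only as spread between libraries. In transcripts with at least 10 reads, the effective length exceeded the length for 26.5% to 28.7% of transcripts, depending on the library, which needs a bias model in the quantifier. Transcripts of at least 1000 bases with no reads mostly had an effective length under 200 bases (19695 of 23054 in control replicate 1), so effective lengths of transcripts without reads were not used.

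The IDs are 203027 Ensembl transcript IDs and 1 RefSeq accession, and nothing used here pairs the Ensembl transcript IDs with genes. The tests were planned on gene sums. They were run on transcripts instead, with the same model, filter, normalization and threshold, and the alternatives fixed for genes before the data were examined were applied to transcripts. PRPF39, transcript usage within genes, splicing events, splice site strength, transcript biotypes, gene lists and gene length were planned and were not analysed here. The RefSeq accession was matched without its version to the reference table of assembly GRCh38.p14.

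Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): filterByExpr by group with its default minimum count of 10, TMM normalization, and the quasi-likelihood test of group over all 6 libraries with no covariate. Benjamini-Hochberg adjusted p under 0.05 was called. Normalized abundance is in CPM, counts scaled to library size with TMM factors, and log2 CPM used a prior count of 2. Standard errors of log2 fold changes were the fold change divided by the square root of the test's F. Of the transcripts, 97571 were tested, and they held 99.84% to 99.88% of the estimated counts of each library. Library totals ran from 113747941 to 246491084 estimated counts. In counts simulated from the means, library sizes and dispersions of this comparison, with 100 transcripts changed 2-fold and 100 changed 4-fold among those of at least 1 CPM, the test recovered 9% of the 2-fold and 53% of the 4-fold changes and called 5 unchanged transcripts among 91851 tested. When the filter asked for a mean of at least 5 CPM, it recovered 46.3% and 95% of the changed transcripts that passed that filter, and called 7 unchanged among 20179 tested.

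Transcripts named in the text follow a rule fixed before the data were examined: adjusted p under 0.05, a mean of at least 10 CPM, no overlap between the groups' values, ranked by log2 fold change. Since no gene names go with the IDs, the 12 per direction of that rule were reduced to the first 2 per direction, and the RefSeq record was added because it alone matched a gene. Library measures (share of TPM by transcript length, transcripts detected) were compared by exact two-sided permutation tests, where 3 libraries against 3 cannot give a p under 0.1. Lengths of called transcripts were compared by a permutation test of the difference of medians with 100000 resamples. Libraries were compared pair by pair: the chi-square per degree of freedom of their counts was at least 32.4, far above the value of 1 that resampling of 1 library would give, so no library was counted as a duplicate.

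The alternatives were size factors in the style of DESeq2 (RLE) and upper-quartile normalization, no filter beyond 1 read, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom (limma 3.58.1), offsets from effective lengths, a replicate block, a 2-fold threshold, and leaving out each library. Thinning all libraries to the smallest total, and the alternatives run on transcripts of at least 5 CPM, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.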

Results

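The data describe how transcript levels in HEK293 cells differ when PRPF39, a factor associated with the U1 small nuclear ribonucleoprotein that recognises 5' splice sites, is targeted by an shRNA. There were 3 control shRNA libraries and 3 PRPF39 shRNA libraries. The control libraries held 158588987, 160302853 and 165751423 estimated counts for replicates 1, 2 and 3, and the PRPF39 shRNA libraries held 191602680, 113747941 and 246491084. Between 118020 and 128309 of the 203028 annotated transcripts had reads in a library. The level of PRPF39 itself was not analysed here, because its transcripts were not matched to their IDs, so the depletion behind the group labels was not checked.

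The first comparison asked how far the libraries of the 2 groups stood apart as wholes. Among 20216 transcripts with a mean of at least 5 CPM, which held 93.1% of the counts, the first principal component took 46.5% of the variance and placed all 3 PRPF39 shRNA libraries (31.9 to 38.9) on the other side of all 3 control libraries (-60.5 to -16.5). Control replicate 3 lay farthest out. The correlation of log2 CPM was 0.932 to 0.962 between libraries of 1 group and 0.89 to 0.943 between groups. The mean within-group correlation exceeded the mean between-group correlation by 0.0338, and the highest of the other 9 splits of the 6 libraries gave 0.0054 (exact one-sided permutation p = 0.1, the smallest that 10 splits allow). Over all 97571 transcripts tested the same excess was 0.0157 against at most 0.0044 in the other splits.

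**Figure D1:**
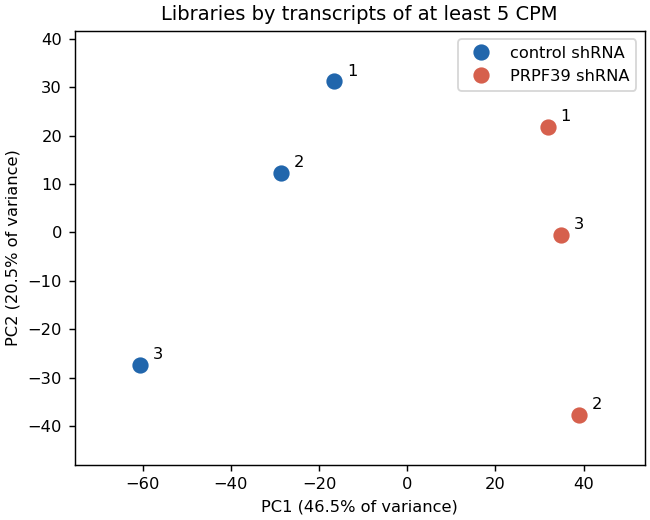
Principal components of log2 CPM over transcripts with a mean of at least 5 CPM. Each point is 1 library with its replicate number, PC1 (46.5% of the variance) is on the x axis and PC2 (20.5%) on the y axis, and the control and PRPF39 shRNA libraries lie on opposite sides along PC1.

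The make-up of the libraries differed between groups by less than the SD of the control libraries, for transcript length classes and for the numbers of transcripts detected alike. Transcripts of up to 500 bases held 16.6% ± 0.96 (SD, n = 3) of TPM in control and 16.9% ± 0.61 (SD, n = 3) in PRPF39 shRNA libraries (exact permutation p = 0.7). Transcripts over 4000 bases held 6.05% ± 0.75 and 6.21% ± 0.30 (SD, n = 3 each, exact permutation p = 0.8). The number of transcripts at 1 TPM or more was 45870 ± 2549 in control and 45150 ± 965 in PRPF39 shRNA libraries (SD, n = 3 each, exact permutation p = 0.7). None of the 8 such measures could have passed at 0.05, since 3 libraries against 3 cannot give a p under 0.1. The lowest adjusted p of these exact permutation tests was 0.914. The 12 most abundant transcripts, 200 to 1542 bases long, included none that was called by edgeR's quasi-likelihood test over all 97571 transcripts tested. Their outcome when transcripts of at least 5 CPM were tested on their own is not given here. Their log2 fold changes ran from -0.28 to 0.46. The transcript with the highest mean, 207 bases long, stood at 18660 ± 3424 TPM in control and 24360 ± 2981 TPM in PRPF39 shRNA libraries (SD, n = 3 each, adjusted p = 0.162, edgeR). The next, 684 bases long, stood at 10054 ± 1060 TPM in control and 14125 ± 1054 TPM in PRPF39 shRNA libraries (SD, n = 3 each). Its log2 change was 0.46 ± 0.09 (SE), and its adjusted p of 0.0787 (edgeR) was the lowest of the 12.

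The second comparison asked which transcripts changed in level. With PRPF39 shRNA 432 transcripts were higher and 450 were lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), which is 0.9% of the 97571 tested. A fold change of at least 2 was reached by 268 of the higher and 293 of the lower transcripts, and the median absolute log2 change was 1.23 and 1.22. All 882 had no overlap between the values of the 2 groups, which a call nearly requires with so few libraries. Of all transcripts tested, 25.3% had no overlap. The calls lay mostly among abundant transcripts: 575 of the 882 had a mean of at least 5 CPM, and the median abundance of the higher and lower sets was 12.7 and 13 CPM. The number fell to at most 22 whichever library was left out, so the fall was not tied to a particular library. Without control replicates 1, 2 and 3 in turn it was 21, 9 and 11, and without PRPF39 shRNA replicates 1, 2 and 3 it was 22, 1 and 0, although 11672 transcripts still had an unadjusted p under 0.05 without PRPF39 shRNA replicate 3. DESeq2 on the same transcripts called 4898 higher and 4126 lower.

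**Figure D2:**
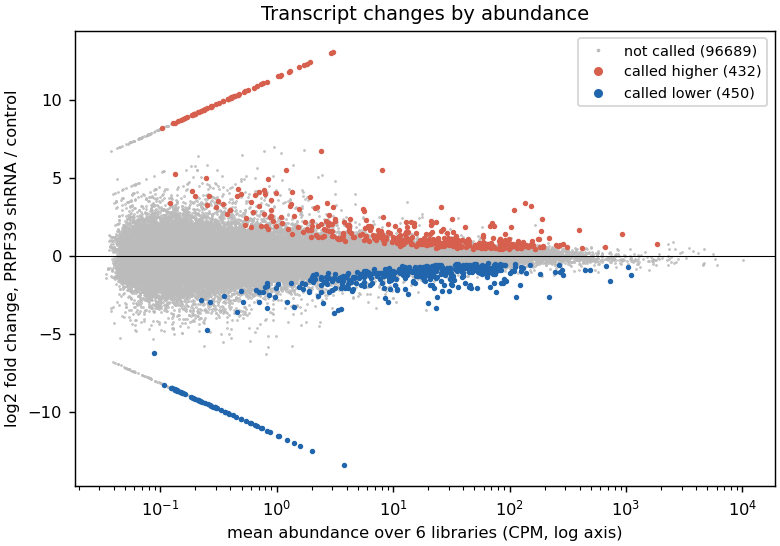
Log2 fold change of PRPF39 shRNA over control (y axis) against the mean abundance in CPM (x axis, log scale) for the 97571 transcripts tested. Orange and blue points are the 432 transcripts called higher and the 450 called lower, and the slanted arms at the top and bottom are transcripts at or near 0 counts in 1 group, whose fitted fold depends on the prior count.

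Tested on their own, transcripts of at least 5 CPM gave more calls. Of 20216, 1730 were higher and 1845 were lower with PRPF39 shRNA (edgeR's quasi-likelihood test, adjusted p under 0.05), or 17.7%. All 575 calls of the wider test at this abundance were among them, with the same direction. Most of the changes were small, with a median absolute log2 change of 0.61, and 184 of the higher and 324 of the lower transcripts changed at least 2-fold. Leaving out control replicates 1, 2 and 3 in turn gave 4269, 1910 and 1702 calls, and leaving out PRPF39 shRNA replicates 1, 2 and 3 gave 1988, 1416 and 879. The share of higher calls was 48.4%, against 49% in the wider test. With upper-quartile normalization that share was 58.3% of the calls of the wider test and 44.3% of those at 5 CPM.

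The tested transcripts were then divided by mean abundance into 5 classes of equal number. The share of transcripts whose groups did not overlap rose with abundance. In the least abundant class, from 0.0346 to 0.157 CPM, 15.1% of transcripts had all 3 PRPF39 shRNA libraries above or below all 3 controls. In the most abundant class, from 5.38 CPM upward, the share was 41.1%. Chance alone gives 10% for 3 libraries against 3. The other 9 splits of the libraries gave 8.53% to 11.2% in the least abundant class and 2.19% to 15.8% in the most abundant. Each transcript without tied values is apart in a single split, so a high share in the real split lowers the others. The other splits are therefore no independent reference for it. Calls followed the same order, with 23 in the least abundant and 569 in the most abundant class.

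**Figure D3:**
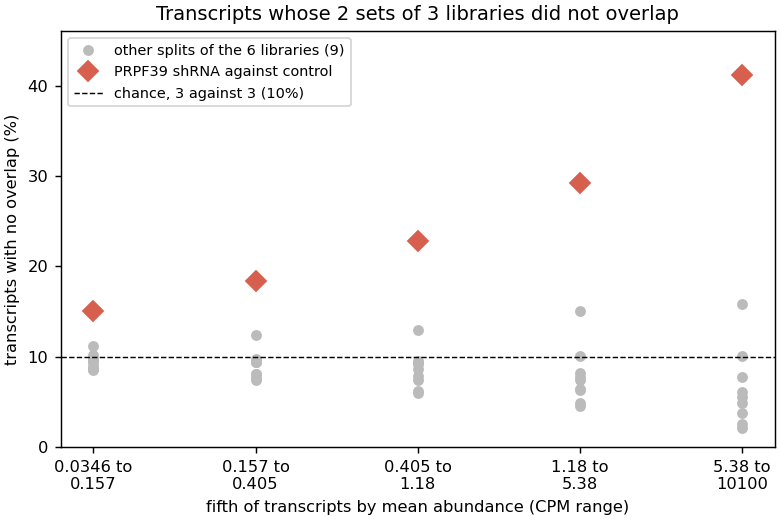
Percent of transcripts (y axis) with no overlap between 2 sets of 3 libraries, for 5 equal classes of mean abundance in CPM (x axis). Diamonds are PRPF39 shRNA against control, grey points the other 9 splits of the 6 libraries, and the dashed line the 10% that chance gives. The diamonds lie above every grey point in each class, but a high diamond lowers the grey points, since each transcript without tied values is apart in a single split.

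The changes of single transcripts reached about 10-fold at moderate abundance. Among the 234 higher and 246 lower calls that met the rule for naming, ENST00000371697 (1979 bases) rose most, from 23.7 ± 5.24 CPM in control to 249 ± 76.2 CPM in PRPF39 shRNA libraries (SD, n = 3 each), a log2 change of 3.39 ± 0.28 (SE; adjusted p = 0.0181, edgeR). ENST00000370683 (2565 bases) rose from 29.4 ± 9.67 to 274 ± 111 CPM (SD, n = 3 each), a log2 change of 3.22 ± 0.40 (SE; adjusted p = 0.0335, edgeR). The largest fall was that of ENST00000335174 (1141 bases), from 42.4 ± 18.0 to 4.3 ± 0.57 CPM (SD, n = 3 each), a log2 change of -3.30 ± 0.32 (SE; adjusted p = 0.0219, edgeR). ENST00000290271 (3883 bases) fell from 35.3 ± 5.81 to 4.4 ± 1.5 CPM (SD, n = 3 each), a log2 change of -2.99 ± 0.28 (SE; adjusted p = 0.0205, edgeR). With 1 library left out in turn, ENST00000371697 passed the threshold only without PRPF39 shRNA replicate 1 (adjusted p = 0.0394, edgeR) and ENST00000335174 only without control replicate 1 (adjusted p = 0.0488, edgeR). The other 2 passed in none of the 6, with adjusted p from 0.052 to 0.144 (edgeR). The log2 changes of the 4 kept their sign, at 2.94 to 3.59 for the rises and -3.54 to -2.76 for the falls over all alternatives.

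The transcript that could be placed on a gene was not called. It is the RefSeq record NM_001162371.2 of LOC728392, a protein-coding locus on chromosome 17 from 5499427 to 5501006 in GRCh38.p14, and it is 1503 bases long in the files. It stood at 17.3 ± 1.17 CPM in control and 18.6 ± 0.25 CPM in PRPF39 shRNA libraries (SD, n = 3 each), a log2 change of 0.10 ± 0.09 (SE; adjusted p = 0.667, edgeR).

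**Figure D4:**
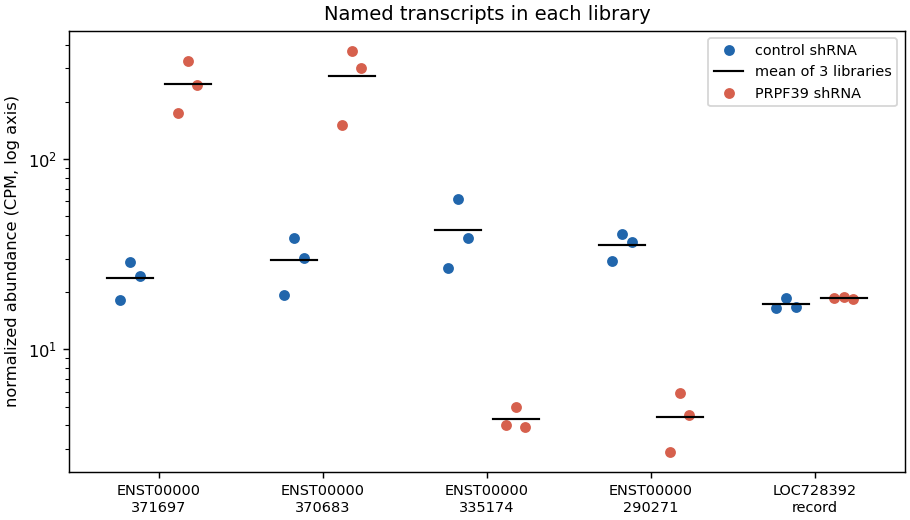
Normalized abundance in CPM (y axis, log scale) of the 4 named Ensembl transcripts and the LOC728392 record in each library. Blue and orange points are the control and PRPF39 shRNA libraries and black lines the means of 3; ENST00000371697 lies at 18.2 to 28.7 CPM in control and 175.6 to 327.8 CPM in PRPF39 shRNA libraries.

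In a comparison chosen after the data were seen, the transcripts called lower were longer than those called higher. The median length was 3236.5 bases for the 450 lower transcripts and 2336.5 bases for the 432 higher ones, a difference of 0.47 on the log2 scale (permutation test with 100000 resamples, two-sided, p = 1e-05, the smallest it can give). That p treats transcripts as independent. When the 6 libraries were split in other ways and the 882 transcripts with the lowest p were taken, 3 of the other 9 splits gave a difference as large, up to 0.972. Among the transcripts called by DESeq2 the difference was 0.09. A correlation planned across protein-coding genes with gene length was run instead across all 97571 transcripts with transcript length. Spearman's rho between transcript length and log2 fold change was 0.005 (permutation test with 100000 resamples, two-sided, p = 0.108). The sign of rho reversed in 4 of 8 alternatives. Of the called transcripts of 3073 bases or more, the longest of 5 classes of about equal number, 142 were higher and 236 lower. In the class from 1769 to 3072 bases 143 were higher and 92 lower.

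A further 124 of the 882 calls, 63 higher and 61 lower, had at most 3 counts in every library of 1 group, so their fold changes have no fixed size. Over all transcripts, 48 had at least 50 counts in every PRPF39 shRNA library and at most 3 in every control library, and 35 showed the reverse. The total of 83 compares with 32 to 66 in the other 9 splits of the libraries.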

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

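The alternatives run on transcripts of at least 5 CPM and the thinning of libraries were chosen after the data were seen. The 432 higher and 450 lower transcripts stayed within 1.5 times these counts with RLE size factors, upper-quartile normalization, no low-count filter, limma-voom, effective-length offsets and libraries thinned to the smallest total. With a mean of at least 5 CPM the counts were 1730 and 1845, with DESeq2 4898 and 4126, and with a 2-fold threshold as well 268 and 293. DESeq2 called 158 to 888 transcripts in the other 9 splits of the libraries, where edgeR and limma-voom called 0. Those splits mix the 2 groups in each set, so a group difference adds to their spread, and their calls do not measure false calls. The replicate numbers were not taken as pairs, because the labels do not say that a number marks a shared culture, day or batch. Deviations from the group means of libraries with the same replicate number correlated at 0.07, 0.02 and 0.01 (numbers 1, 2 and 3). With the replicate block 0 were higher and 0 lower, with 14264 at an unadjusted p under 0.05 (edgeR). All 882 calls kept their sign under that block, and the 4 named transcripts had adjusted p from 0.12 to 0.18 (edgeR). Leaving out each library gave 0 to 14 higher and 0 to 12 lower. In simulated counts the test recovered 29% to 36% of 4-fold changes with 5 libraries and 53% with 6, and for 2-fold changes at most 2% and 9%. Only 100 transcripts per fold were changed there, while 15743 had an unadjusted p under 0.05 in the data (edgeR). The simulation therefore cannot account for the calls lost with a library. Among transcripts of at least 5 CPM, RLE, upper quartile, limma-voom, effective-length offsets and the replicate block (1564 and 1818) stayed within 1.5 times the counts, DESeq2 gave 2688 and 2895, and leaving out each library gave 393 to 2048 higher and 486 to 2221 lower. Where upper-quartile normalization moved the share of higher calls, the median log2 change moved in the same direction. It moved from -0.024 to 0.019 over all tested transcripts and from 0 to -0.016 over those of at least 5 CPM. Transcript length and log2 fold change correlated across transcripts at Spearman's rho = 0.005 (permutation p = 0.108, 100000 resamples; transcripts are not independent replicates). It was 0.021 with effective-length offsets, -0.037 at 5 CPM, and -0.023 to 0.035 over the 6 fits that left out a library; the cause was not tested. The cause of the differences between tools was not tested either. The planned gene-level, splicing-event, splice-site, biotype and gene-list alternatives were not run.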

Other observations

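Of the tests below, those with effective-length offsets and with the library length trend removed had their predictions set before their results were seen, and the others were chosen after. Splits of the libraries could not set the number of calls against chance at the 0.05 level, since 6 libraries make 10 splits. The adjusted p-values of edgeR do so only through its model of the spread between libraries. In counts simulated from that model, 5 unchanged transcripts were called among 91851 tested, beside 9 of the 2-fold and 53 of the 4-fold changes. Among 20179 of at least 5 CPM, 7 unchanged transcripts were called, beside 25 and 57 changed ones. Since those counts came from the model, they cannot show whether it holds for these libraries. The real split alone, 1 of the 10, gave 882 calls, and the highest of the others gave 0. Among transcripts of at least 5 CPM it gave 3575, again 1 of the 10, and the highest of the others gave 1. Each of the other splits mixed libraries of both groups in each set. A difference between the groups would add to the spread there and lower the calls, so these low numbers do not measure chance.

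The greater length of the transcripts that fell was weighed as a hypothesis about transcript length. Library differences in the quantifier's effective lengths are argued against, since the log2 length difference was 0.443 with effective-length offsets against 0.47 without (permutation p = 1e-05). A difference in abundance is argued against as well, since the median abundance of the higher and lower sets was 12.7 and 13 CPM. There was thus little to adjust for, and the length difference relative to transcripts of like abundance was 0.425 (permutation p = 1e-05). Both of these p-values treat transcripts as independent. A length trend of whole libraries stays open. Each library's trend was fitted to its deviation from the mean of all libraries, so its removal also takes out any effect of the group on length. The test therefore cannot tell a library trend from such an effect. With each library's trend removed, 563 transcripts were called higher and 414 lower. The difference between these changed sets was 0.217 (permutation p = 0.0121). By the rules set in advance, the size of this fall from 0.47 counted for the trend and the p against it. That p assumes independent transcripts, while without trend removal 4 of the 10 splits, the real one included, gave a difference of at least 0.47. A direct effect of PRPF39 shRNA on long transcripts also stays open and was not tested, because gene models were not used here.

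Transcripts present in 1 group and near absent in the other look like complete switches, but a candidate explanation is read allocation that varies between libraries without regard to group. It would give such transcripts in any split, and the other splits held 32 to 66, with a median of 46, against 83 in the real one. Of those 83, 78 were called. EdgeR called 0 transcripts in the other splits, but these mix the groups in each set, which adds spread, so that 0 is no contrast. The counts behind these totals were not scaled for depth. The split with the 66 set control replicate 1 and PRPF39 shRNA replicates 1 and 3 against the rest. It also gave the highest share of transcripts without overlap among the other splits in the most abundant of the 5 classes, 15.8%. PRPF39 shRNA replicates 1 and 3 had the most counts of all libraries, and PRPF39 shRNA replicate 2, on the other side, the fewest. Their side held 46 of the 66, and depth was not tested as a cause. The excess of the real split over 66 stays open, since the files give no bootstrap estimates for these transcripts.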
